A study of Homo sapiens with 6 samples.

How the data were processed

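U251 is an established human glioblastoma cell line. Per the labels, cells were made stable carriers of a lentiviral short hairpin RNA, either against the long non-coding RNA LINC01116 (sh-LINC01116) or a non-targeting one (sh-NC). The 2 groups held 3 samples each, and each sample was hybridised to 1 array. Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was amplified by random priming and labelled with a single dye, and the arrays were one-colour Agilent whole-genome expression arrays. The labels do not say that samples of a group came from separate cultures, so that all p-values measure only the spread between these samples, which may be technical.

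The deposited scanner files held spot intensity values on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the file headers, one file per array. The processed intensity in these files had its background subtracted and a spatial trend removed per the file headers, and was not normalized between arrays. The authors also deposited a table of log2 values. Each of its columns correlated with the log2 processed intensity of the same array at r above 0.994, with slopes of 0.98 to 1.02, and the columns shared 1 distribution with a median of 6.77, so that the scale was log2, the arrays had been quantile normalized and genes had not been centred. The step that made this table is not given in the sources used here. These log2 values served as an alternative.

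Each array held 44495 spots, of which 43118 were not controls. They stood for 34127 probes. Between 228 and 805 spots per array carried an outlier mark and were left out, and no spot was saturated. Brightness differed between arrays, with a 75th percentile of the processed intensity of 2005 to 2026 on the sh-NC arrays, 1916 on sh-LINC01116 2, 733 on sh-LINC01116 1 and 636 on sh-LINC01116 3. The share of probes well above background was 79.0% to 82.4% on the sh-NC arrays and 73.7% to 82.9% on the sh-LINC01116 arrays. The number of arrays limits the precision.

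The scan records placed the arrays on 3 slides. Slide 1 held the 3 sh-NC arrays and sh-LINC01116 2, slide 2 held sh-LINC01116 1 and slide 3 held sh-LINC01116 3. A comparison free of the slide therefore rests on 1 sh-LINC01116 array against 3 sh-NC arrays. With the slide as a fixed block, the fold change is the within-slide one, and the random block used the correlation of arrays on the same slide, 0.77, estimated by duplicateCorrelation. That estimate rests on slide 1, which held mostly sh-NC arrays, and cannot separate slide from a smaller spread in sh-NC.

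For the main values, the log2 processed intensity of each spot had the 75th percentile of its array subtracted, and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 of the 6 arrays. The files hold no gene symbols, so probes were named through the transcript accession of the array design and the RefSeq gene table of assembly GRCh38.p14, used for names and gene order only. That table named 25771 probes (75.5%) and left 8356 unnamed. For a gene with several probes the brightest one stood for the gene, and 4047 genes had more than 1 probe. The fit ran on 16699 named genes.

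Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a block), and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and a second count asked for at least a 2-fold change. Fold changes are sh-LINC01116 over sh-NC. A gene not well above background on every array of one group, and well above it on all arrays of the other, has only a bound. There the mean of the brighter group was set against the mean over the dimmer group of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

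A set of 30 gene lists was fixed before the data were examined, and the 29 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list moves one way on balance, were alternatives. The lists covered neighbours of LINC01116, interleukin-1 and chemokine genes, NF-kappa-B feedback, interferon response, antigen presentation, DNA replication, mitosis, histones, p53 targets, apoptosis, matrix and invasion, TGF-beta targets, hypoxia and glycolysis, the unfolded protein response, sterol and lipid synthesis, oxidative phosphorylation, ribosomal proteins, immediate early genes, heat shock, oxidative stress, angiogenic and growth factors, glioblastoma subtypes, glial, neuronal, epithelial, macrophage, and endothelial or fibroblast markers, and housekeeping genes. The remaining list held 3 genes (IL1B, DDX5 and VEGFA) and was too small to test.

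Genes are named by a rule set before the data were examined. It takes LINC01116, the 12 largest rises and 12 largest falls among called genes detected on all 6 arrays without overlap of the groups, IL1B, DDX5 and VEGFA, up to 4 members of smallest adjusted p in each list, and in each direction the 5 largest bounds among genes measured in one group only. Names outside this rule are marked as chosen after their values were seen.

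Alternatives set before the data were examined were quantile normalization, scaling to the array median, normexp background correction (offset 50) with either scaling, the authors' log2 values, other filters on dim probes, other ways to join probes, limma with a trend, robust limma, array weights, a block for replicate number or slide, other thresholds, and leaving out each array. The files used here have no mean spot signal, so normexp was run on the median spot signal and the median local background. Testing unnamed probes, the first slide alone, and sh-LINC01116 1 and 3 alone against sh-NC were added after seeing the data. The last of these is the same fit as leaving out sh-LINC01116 2. The fit was tested on simulated data for sh-LINC01116 against sh-NC with 16699 genes. It recovered 58% of 100 genes changed by 1 on the log2 scale and 88% of 100 genes changed by 2, with 5 false calls. The simulated noise was normal, independent between genes and arrays, and of equal spread in both groups. It held no effect of slide or brightness, so that its false calls do not measure those in these data. Figures were drawn with matplotlib 3.10.9.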

Results

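Expression was measured on 6 one-colour arrays of the glioblastoma line U251. Cells carried a lentiviral short hairpin RNA against LINC01116, a long non-coding RNA transcribed beside the HOXD gene cluster, or a non-targeting hairpin. Each group held 3 arrays, here called sh-LINC01116 1 to 3 and sh-NC 1 to 3. The comparison asks which transcripts differ in level when LINC01116 is knocked down. The 3 sh-NC arrays and sh-LINC01116 2 shared slide 1, and the other sh-LINC01116 arrays lay on slides of their own with less signal (a 75th percentile of 733 and 636, against 1916 on sh-LINC01116 2 and 2005 to 2026 on the sh-NC arrays). Within-slide values, from sh-LINC01116 2 against the 3 sh-NC arrays, are therefore given beside the pooled ones. In 72.6% of genes sh-NC 1 lay between sh-NC 2 and sh-NC 3, where 3 independent arrays of equal spread give 33.3% (30.7% to 37.3% for the sh-LINC01116 arrays). Its median distance from their mean was 0.03 on the log2 scale. It may therefore add little independent spread, and p-values that count 3 sh-NC arrays may be too small, so that fits without sh-NC 1 are given below. The fit with the slide as a block rests on sh-LINC01116 2 alone against the sh-NC arrays. Its p-values take their spread from sh-NC only, assume that the lone array varies alike, and are no independent support.

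LINC01116 was lower on each of the 3 sh-LINC01116 arrays than on any sh-NC array. Its single probe (transcript NR_040001 in the array design) had a normalized log2 signal of 0.94 ± 0.18 (SD, n = 3) in sh-NC and -0.83 ± 0.31 (SD, n = 3) in sh-LINC01116. The log2 fold change was -1.76 (SE 0.18), or 3.39-fold lower, which left 29.5% of the sh-NC level (limma adjusted p = 0.00947). Within slide 1 the value was -1.79, which left 28.9%. An exact two-sided permutation test of this single gene gave p = 0.1, the smallest that 3 against 3 arrays can give. The adjusted p was 0.083 without sh-NC 1 and 0.052 without sh-NC 2, with log2 fold changes of -1.77 and -1.85.

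**Figure D1:**
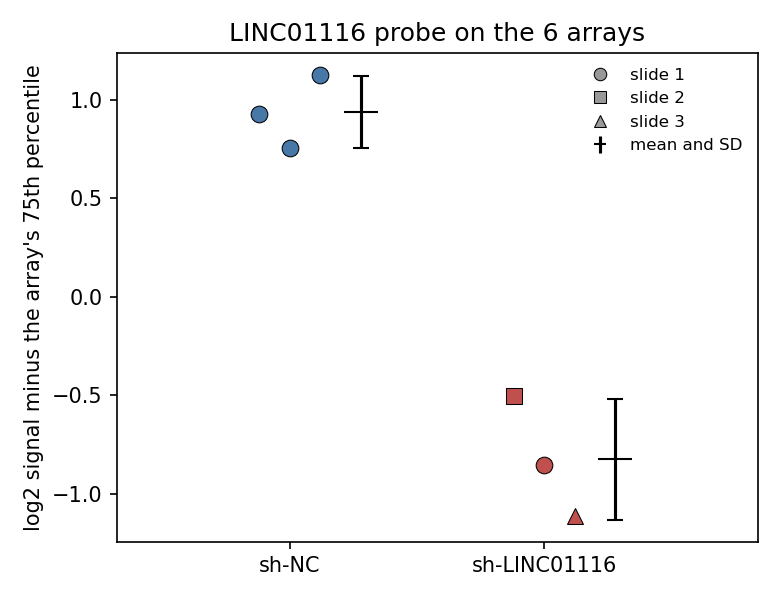
Normalized log2 signal of the LINC01116 probe (vertical axis, log2 signal minus the array's 75th percentile) on each of the 6 arrays, by group. Marker shapes give the slide, and bars give the group mean and SD. The sh-NC arrays sit between 0.76 and 1.12, and the sh-LINC01116 arrays between -1.12 and -0.50.

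Across the 16699 genes tested, 1558 changed (9.33%), of which 684 were higher and 874 lower in sh-LINC01116. Of these, 382 changed at least 2-fold (146 higher and 236 lower). Groups did not overlap in 6957 genes (41.7%), the called ones included. Chance gives 10% only where all arrays are independent and of equal spread. That is in doubt here, since sh-NC 1 lay between the other sh-NC arrays in 72.6% of genes. The correlation of arrays on the same slide was estimated at 0.77. Only slide 1 held more than 1 array, so this value cannot be told apart from a smaller spread among the sh-NC arrays. The chance share for arrays that are not independent or differ in spread was not estimated, so that the excess over chance is not known. Among called genes, the median log2 fold change was 0.72 for those higher and -0.74 for those lower, and the within-slide medians were 0.60 and -0.71. The signs of the within-slide medians were fixed by the selection, since the groups overlapped in no called gene. The median of all genes lay at 0.10 and within the slide at 0.01. It moved to -0.06 when arrays were scaled to their median, to -0.02 under quantile normalization, to -0.04 in the authors' values and to 0.25 with normexp background correction and the same scaling, so that a gene counts as moving with or against the rest only beyond these shifts. The share of called genes that were higher was 43.9%, and became 33.3% of 1864 genes under quantile normalization, 23.7% of 1412 with median scaling, 30.3% of 1823 in the authors' values and 70.5% of 4502 without sh-LINC01116 2. With the slide as a fixed block 333 genes were called (87 higher and 246 lower), and with the slide as a random block 2061.

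The number of calls depended on single arrays. Only GLDN was called without sh-NC 1 or without sh-NC 2, while 356 genes were called without sh-NC 3, 940 without sh-LINC01116 1 and 642 without sh-LINC01116 3. At 2-fold, 1538 genes were called without sh-LINC01116 2 and 242 without sh-LINC01116 3. In each of these fits all 1558 genes kept an unadjusted limma p under 0.05. Their direction could not turn, since the groups overlapped in no called gene. These fits also share most arrays with the one that chose the genes, so neither result is independent support. The median adjusted p of the 1558 genes was 0.166 without sh-NC 1 and 0.101 without sh-NC 2. The genes named below as changed are among the 1558. Of those given as a bound in the last paragraph, only the ones with an adjusted p under 0.05 are. Without sh-NC 1, 197 genes had an adjusted p under 0.10, and each of the 8 gene lists called with all arrays was called. With normexp background correction and the same scaling 176 genes were called, 175 of them among the 1558. In that setting only 1420 of the 1558 kept their direction.

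The largest falls were those of PI15, a secreted peptidase inhibitor (log2 fold change -3.51, SE 0.33, 11.4-fold lower, limma adjusted p = 0.00781), CA9, a carbonic anhydrase induced by low oxygen (7.50-fold lower), MGP, a matrix protein that inhibits calcification (7.21-fold lower), and GLDN, an adhesion protein of the node of Ranvier (-2.79, SE 0.10, 6.90-fold lower, adjusted p = 0.00103). Next came the growth factor binding protein IGFBP5 (6.73-fold lower), the water channel AQP1 (5.10-fold), the keratin KRT15 (5.05-fold), the astrocyte filament protein GFAP (4.96-fold), the kinase ALPK3 (4.64-fold), the neuropeptide Y receptor NPY1R (4.42-fold), the apoptosis inducer BMF (4.42-fold) and FILIP1L (4.12-fold). AQP1 and BMF each had a second probe that went the other way without passing the test. Within slide 1 these 12 genes had log2 fold changes from -1.95 to -3.57. With normexp background correction 5 of the 12 falls passed the test and that of BMF was -0.20.

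The largest rises were those of CPED1 (log2 fold change 2.56, SE 0.14, 5.92-fold, limma adjusted p = 0.00622), the growth factor FGF1 (2.52, SE 0.24, 5.72-fold), the lipase MGLL, which breaks down monoacylglycerols (4.56-fold), and the ubiquitin ligase MARCHF4 (4.42-fold). GDF6, a ligand of the bone morphogenetic protein family, rose 4.08-fold, and NOG, an antagonist of that family, rose 3.33-fold. CYP3A4 rose 3.95-fold, EVI2B 3.53-fold, the nuclear receptor NR5A2 3.44-fold, the sphingosine kinase SPHK1 3.40-fold, the anchoring protein AKAP5 3.36-fold and the cytokine subunit IL12A 3.33-fold. Within slide 1 these rises ran from 1.16 (NR5A2) to 2.41 (CPED1) on the log2 scale. With normexp background correction 8 of the 12 rises passed the test. Several of these genes were dim. The sh-NC mean of the normalized log2 signal was -6.48 for IL12A, -5.95 for CPED1 and -5.84 for NR5A2. It was -5.45 for NOG and -5.16 for AKAP5, where the median of tested genes on sh-NC 1 was -1.35. For such genes the rise on the dimmer arrays depends on the scaling. That of IL12A was 0.52 with normexp and quantile normalization, and 1.59 within slide 1.

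**Figure D2:**
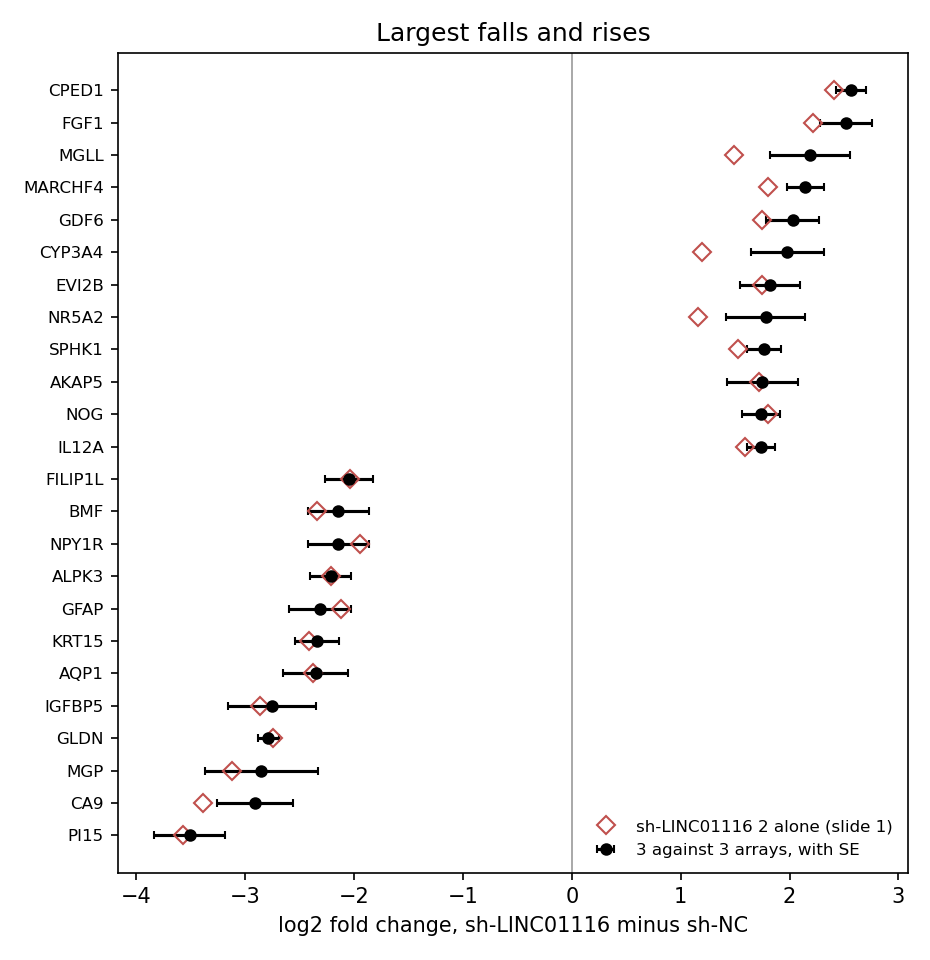
Log2 fold change (horizontal axis, sh-LINC01116 minus sh-NC) of the 12 largest falls and 12 largest rises. Filled points give the fit of 3 against 3 arrays with its SE, and open diamonds give sh-LINC01116 2 against the sh-NC arrays of the same slide. Falls run from -3.51 (PI15) to -2.04 (FILIP1L) and rises from 1.73 (IL12A) to 2.56 (CPED1). The diamond lies on the same side of 0 in each gene, which was fixed by choosing genes without overlap of the groups.

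Genes of hypoxia and glycolysis were lower. Of 34 tested, 8 fell and none rose, and with p-values adjusted over the list alone 14 fell and 1 rose. Examples are DDIT4, an inhibitor of mTOR signalling (4.03-fold lower), NDRG1 (2.19-fold), BNIP3L, a mitophagy receptor (1.75-fold), and VEGFA, the vascular growth factor (log2 fold change -1.63, SE 0.21, 3.09-fold lower, limma adjusted p = 0.0135, within slide -1.58). The median of the list was -0.23 (within slide -0.21), with a camera adjusted p = 2.98e-05 and an adjusted p = 0.574 with an estimated correlation.

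Genes of the interleukin-1 and neutrophil chemokine list were higher. Of 19 tested, 7 rose and none fell, and 13 rose with p-values adjusted over the list alone. Among them were the neutrophil attractants CXCL8 (2.28-fold, log2 SE 0.13, limma adjusted p = 0.00984) and CXCL3 (1.73-fold), the pentraxin PTX3 (2.17-fold) and the cytokine IL11 (1.90-fold). The median was 0.79 (within slide 0.40), with a camera adjusted p = 1.29e-05 and an adjusted p = 0.442 with an estimated correlation. The size depended on the scaling. The median was 0.63 with median scaling, 0.46 under quantile normalization, 0.43 in the authors' values and 0.29 with normexp and quantile normalization. With normexp and the 75th percentile it was 0.88. IL1B, which encodes interleukin-1 beta and was 1 of the 3 genes fixed beforehand, had a log2 fold change of 1.17 (SE 0.28, higher on 3 of 3 arrays, limma adjusted p = 0.055, within slide 0.79) and did not pass. Its adjusted p ranged from 0.0253 to 0.296 over the alternatives. DDX5, an RNA helicase, had a log2 fold change of 0.21 (SE 0.14, adjusted p = 0.343), which turned negative within the slide (-0.07), under quantile normalization (-0.21), with normexp and quantile normalization (-0.26) and in the authors' values (-0.24). In the list of NF-kappa-B feedback genes 5 of 16 rose, among them TRAF1 (2.01-fold), BIRC3 (1.99-fold) and CD83 (1.98-fold), and 1 fell, BCL3 (2.08-fold lower). These counts were the same with p-values adjusted over the list alone. That list had a median of 0.33 (within slide 0.25) and a camera adjusted p = 0.082. By fry the adjusted p was 0.013. By camera it was 0.043 under quantile normalization, 0.044 with normexp and quantile normalization, 0.040 with median scaling and 0.040 without sh-LINC01116 1. It was 0.720 with an estimated correlation, 0.351 with normexp and the 75th percentile and 0.396 without sh-LINC01116 2.

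Interferon response genes were lower. Of 36 tested, 5 fell and none rose (6 fell with p-values adjusted over the list alone). They included IFIT2 (2.20-fold lower, log2 SE 0.09, limma adjusted p = 0.00651), the exonuclease ISG20 (2.17-fold), PARP9 (2.17-fold) and SAMD9L (1.95-fold). The list's median of -0.76 (within slide -1.10) had a camera adjusted p = 5.39e-08. The adjusted p was 0.745 with an estimated correlation and 0.157 by fry, so that neither alternative called the list. With 1 array left out the median ran from -0.52 (without sh-NC 2) to -1.05 (without sh-NC 3). Of 15 antigen presentation genes none passed the test, with a median of -0.02 and a camera adjusted p = 0.727.

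Genes of DNA replication were higher by small amounts. Of 41 tested, 7 rose and none fell (12 rose with p-values adjusted over the list alone). Among them were MCM10 (1.55-fold), the helicase parts MCM6 (1.53-fold, log2 SE 0.11) and GINS1 (1.39-fold), and the clamp loader part RFC3 (1.37-fold). The median was 0.28 (within slide 0.21), with a camera adjusted p = 0.000339. The adjusted p was 0.104 with normexp and the same scaling and 0.343 with an estimated correlation. Of 39 mitosis genes 1 rose, ANLN (1.41-fold), and none over the list alone, with a median of 0.19. The camera adjusted p was 0.082, with 0.0105 without sh-LINC01116 3, 0.478 without sh-LINC01116 2 and 0.942 with an estimated correlation. It was 0.782 in the other direction with normexp and the 75th percentile. Of 34 histone genes 1 fell, H1-2 (1.79-fold lower), also over the list alone (median 0.23, camera adjusted p = 0.267).

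Members of the p53 and apoptosis lists moved both ways. Of 28 p53 targets 5 rose, among them ZMAT3 (1.64-fold) and GADD45A (1.49-fold), and 4 fell, among them TP53INP1 (1.93-fold lower) and DDB2 (1.40-fold lower), with 8 and 6 over the list alone and a camera adjusted p = 0.952. Of 28 apoptosis genes 3 rose, with the survival factor BCL2 at 2.15-fold and BIRC2 at 1.52-fold, and 2 fell, the apoptosis inducers BMF and BCL2L11 (2.09-fold lower), with 5 and 3 over the list alone and a camera adjusted p = 0.981. BCL2L11 turned to 0.23 on the log2 scale when its probes were averaged.

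Matrix, growth factor and early response genes also went both ways. Of 46 matrix and invasion genes 6 rose and 2 fell (9 and 5 over the list alone, camera adjusted p = 0.910). The integrin ITGB3 rose 2.79-fold and the collagen COL4A1 1.82-fold, while the collagen COL1A2 was 1.58-fold lower. Of 22 TGF-beta targets 5 rose, among them LTBP2 (2.06-fold) and INHBA (1.69-fold), and 2 fell, among them TGFB3 (1.99-fold lower), with 6 and 5 over the list alone and a camera adjusted p = 0.727. Of 27 angiogenic and growth factor genes 3 rose, among them HBEGF (2.11-fold) beside FGF1, and 3 fell, among them the receptor PDGFRA (log2 fold change -1.96, SE 0.22, 3.89-fold lower) beside IGFBP5, with 4 and 4 over the list alone and a camera adjusted p = 0.727. Of 29 immediate early genes 6 rose, among them FOSL1 (2.29-fold) and the phosphatases DUSP5 (2.59-fold) and DUSP4 (1.89-fold), and 1 fell, NR4A2 (1.80-fold lower), with 7 and 1 over the list alone and a camera adjusted p = 0.243 (0.0331 by fry).

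The neighbours of LINC01116 and glial genes were lower as lists, with few members called. Of 14 genes at the HOXD cluster 2 fell, HOXD3 (log2 fold change -0.83, SE 0.14, 1.77-fold lower, limma adjusted p = 0.0232, within slide -0.97) and HOXD10 (1.44-fold lower), and 6 fell over the list alone. Fry did not call the HOXD list (adjusted p = 0.066). The median was -0.10 (within slide -0.20), with a camera adjusted p = 0.0243 and an adjusted p = 0.720 with an estimated correlation. It was 0.063 with the slide as a block, 0.075 in the authors' values, 0.079 when probes were averaged, 0.306 with every probe on its own, 0.054 without sh-LINC01116 2 and 0.078 without sh-LINC01116 3. Of 16 glial and stem markers 2 fell, GFAP and S100B (2.00-fold lower), and 6 fell and 1 rose over the list alone. That list's median was -0.41 (within slide -0.39, camera adjusted p = 0.0140), with an adjusted p = 0.574 with an estimated correlation, 0.055 with the slide as a block, 0.055 in the authors' values and 0.062 without sh-LINC01116 1. Of 11 proneural glioblastoma genes 4 fell, also over the list alone, PDGFRA, PTPRZ1 (2.67-fold lower), SOX4 (1.82-fold) and TCF4 (1.66-fold), with a median of 0.00, a mean of -0.33, a camera adjusted p = 0.0915, 0.011 by fry, 0.044 with normexp and quantile normalization, 0.043 without sh-NC 1, 0.035 with unnamed probes tested too, 0.574 with an estimated correlation and 0.363 with the slide as a block. Of 19 mesenchymal ones 2 rose, among them RELB (1.69-fold), and LGALS3 fell (1.64-fold lower), also over the list alone (camera adjusted p = 0.952).

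Markers of other cell types gave few calls. Of 11 neuronal markers 2 fell, MAP2 (1.81-fold lower) and NEFL (1.65-fold lower), with 3 lower and 1 higher over the list alone (camera adjusted p = 0.425). Of 9 epithelial markers 1 fell, MUC1 (1.99-fold lower), also over the list alone (camera adjusted p = 0.900). None of 10 macrophage markers (median 0.36, within slide -0.12, camera adjusted p = 0.900) and none of 9 endothelial or fibroblast markers (median -0.22, camera adjusted p = 0.727) passed the test, nor over the list alone.

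Genes of lipid synthesis fell in part. Of 32 sterol and lipid genes 6 fell and none rose (8 lower and 1 higher over the list alone), among them the sterol enzyme TM7SF2 (2.71-fold lower), the fatty acid desaturase FADS2 (2.26-fold, log2 SE 0.12, limma adjusted p = 0.00875), the regulator SREBF1 (2.19-fold) and ACLY (1.49-fold). Fry did not call the list (adjusted p = 0.091). The median was -0.03, with a camera adjusted p = 0.0165 and an adjusted p = 0.720 with an estimated correlation. It was 0.183 with the slide as a block, 0.058 in the authors' values and 0.093 without sh-NC 3. Stress lists were not called. Of 30 genes of the unfolded protein response 1 rose (MTHFD2, 1.39-fold) and 2 fell (VLDLR, 1.76-fold lower, and SLC7A11, 1.55-fold lower), with the same counts over the list alone and a camera adjusted p = 0.900. Of 20 oxidative stress genes 1 rose (TXNRD1, 1.40-fold) and 3 fell, among them PGD (1.44-fold lower), with 1 and 5 over the list alone and a camera adjusted p = 0.502. Of 19 heat shock genes HSPB8 rose (1.40-fold) and CRYAB fell (3.20-fold lower), also over the list alone (camera adjusted p = 0.294).

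The shift of ribosomal protein genes was confined to the 2 dimmer arrays, which lay on slides of their own. The camera test called the 77 genes as higher (median 0.48, adjusted p = 0.000138, and an adjusted p = 0.980 with an estimated correlation), with no single gene passing, over the list alone either. The median was 0.00 within slide 1 and 0.69 in sh-LINC01116 1 and 3. The direction turned under quantile normalization (-0.09), with normexp and quantile normalization (-0.12) and in the authors' values (-0.14). Of 61 oxidative phosphorylation genes none passed, over the list alone either (median 0.08, within slide -0.02, camera adjusted p = 0.900, and 0.0106 in the lower direction with normexp and the 75th percentile). Of 15 housekeeping genes TFRC, the transferrin receptor, rose (1.96-fold), also over the list alone (camera adjusted p = 0.294). ACTB had a log2 fold change of 1.60 (SE 0.72, adjusted p = 0.175), with 0.09 within the slide and 2.35 in sh-LINC01116 1 and 3.

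**Figure D3:**
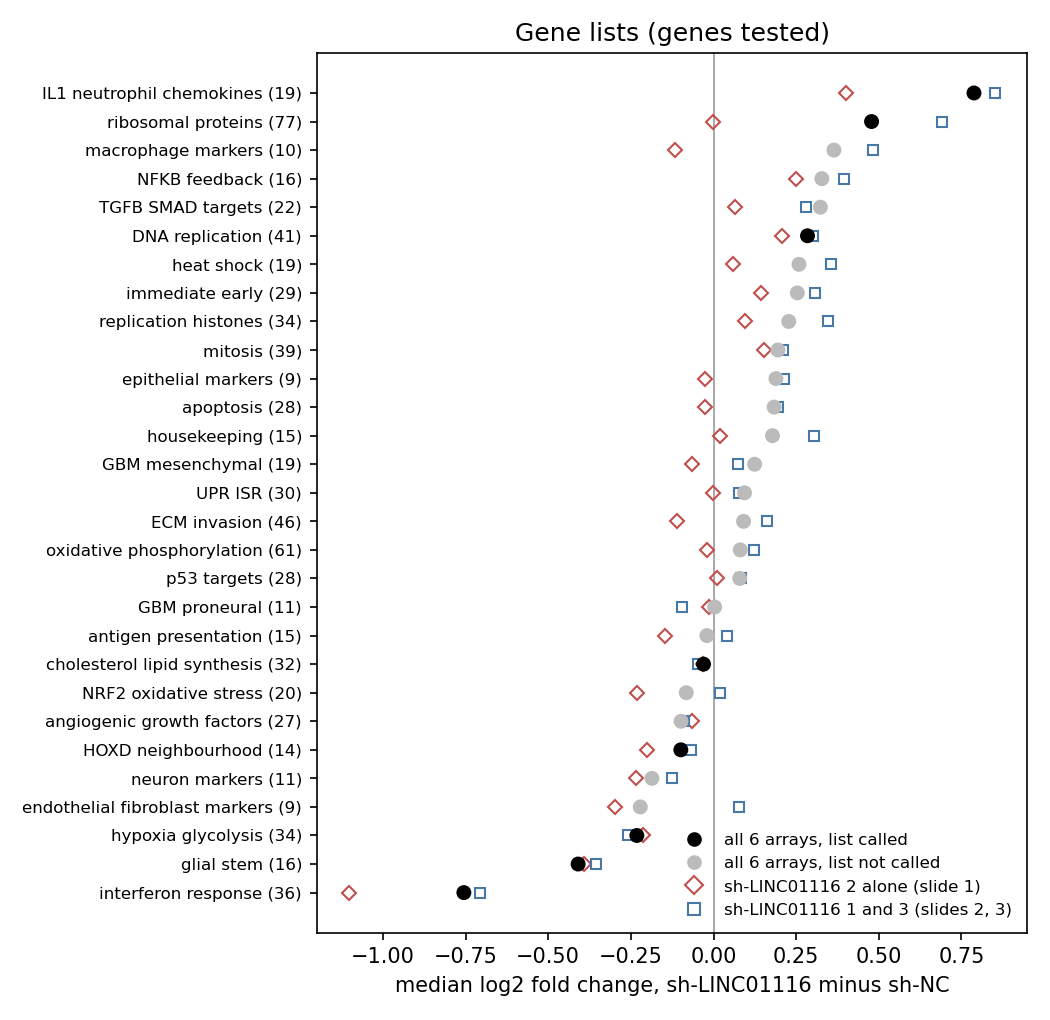
Median log2 fold change (horizontal axis, sh-LINC01116 minus sh-NC) of the genes of each of the 29 lists tested, with the number of genes tested in brackets. Filled points give all 6 arrays (black where camera called the list, grey where not), diamonds sh-LINC01116 2 on slide 1 and squares sh-LINC01116 1 and 3. The interferon list lies lowest (-0.76, diamond at -1.10) and the interleukin-1 and chemokine list highest (0.79, diamond at 0.40), while the diamond of the ribosomal proteins, whose median turns negative under quantile normalization, lies at 0.00.

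A further 42 genes were measured in one group only, with 13 well above background on all sh-LINC01116 arrays and no sh-NC array, and 29 the reverse. Their bounds were small. The small GTPase RAB39A was at least 3.34-fold higher in sh-LINC01116 (limma adjusted p = 0.0113, within slide at least 2.84-fold), NYAP1 at least 3.29-fold (0.077, within slide 1.34-fold), the RNA sensor TLR7 at least 2.59-fold (0.0117, within slide 2.09-fold) and PRAME at least 2.38-fold (0.073, within slide 1.23-fold). The interferon-induced RSAD2 was at least 3.17-fold lower (adjusted p = 0.067, within slide at least 6.35-fold), TPTE2P5 at least 1.81-fold (0.040, within slide 3.40-fold), SERPINA5 at least 1.67-fold (0.035, within slide 3.35-fold) and PSD2 at least 1.59-fold (0.00958, within slide 2.48-fold). LEMD1 had a bound of 1.63-fold lower (0.142, within slide 3.27-fold), but its measured signals overlapped between the groups. With positive and significant in place of well above background 32 genes were found, none of them among the 42. The number was 64 without sh-NC 1, 73 without sh-NC 3, 297 without sh-LINC01116 2 and 100 without sh-LINC01116 3.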

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

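The tests of rising and falling genes apart, of the slide without sh-NC 1, of ribosomal protein genes within the slide, of olfactory receptor genes in sh-LINC01116 2, and of the share of both shifts left with one distribution were chosen only after the result was seen.

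Probes that the reference could not name were outside the comparisons. Of 5986 such probes that passed the filter, 132 were called (85 higher and 47 lower in sh-LINC01116), or 2.21%, against 870 of 16699 named genes (5.21%) in the same fit. No biological explanation was tested for them.

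Groups lay mostly on different slides, so the called genes were tested for chance, slide and brightness. With 10 ways to split the 6 arrays, a share under 0.05 cannot be reached; the real split called 1558 genes, no other split called any (highest 0), so that 1 of the 10 reached that count. For the slide, the 500 top genes of sh-LINC01116 1 and 3 against some sh-NC arrays were followed in a pair from slide 1, sh-LINC01116 2 minus a left-out sh-NC array: 76% to 77% went the same way in the planned form, whose controls are not independent because sh-NC 1 lay near the mean of the others, so that this share decides nothing. Without sh-NC 1, where chance gives about 50%, 66.4% to 70.4% went the same way, 91.9% to 93.8% of the falling genes (lowest 95% bound 84.7%, treating genes as independent) and 60.1% to 63.6% of the rising ones. The slide alone thus falls short for the falls, on the evidence of a single sh-LINC01116 array, while its part in the rises stays open. For brightness, 89.2% of calls kept call and direction under quantile normalization. With normexp and quantile normalization 1180 of the 1558 did so, and with normexp and the 75th percentile 175. Giving arrays one distribution cannot remove effects of dim signal on single probes, and the dimmer arrays lay on other slides. The part of brightness thus stays open. The knockdown, or another effect of the hairpin, remains a hypothesis for the falls.

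Ribosomal protein genes moved as a block in 2 of the 3 sh-LINC01116 arrays. The median shift was 0.35 in sh-LINC01116 1 and 1.05 in sh-LINC01116 3, and -0.00046 in sh-LINC01116 2 on the slide of the sh-NC arrays, and the pooled median turned to -0.093 under quantile normalization. LINC01116 fell in sh-LINC01116 2 as well, which argues against the knockdown as the cause and is what a slide effect needs. In sh-LINC01116 1 and 3, 10000 random lists matched on mean signal themselves shifted by a median of 0.49 (central range 0.40 to 0.64). A large part of the ribosomal shift there (0.69) was thus shared by other genes of equal signal. The shift lay above 99.87% of the lists, but such lists ignore that these genes move together. Giving all arrays the same distribution turned the shift. Whether signal range on dimmer arrays accounts for all of it stays open. A difference in labelling or RNA between slides is a candidate explanation that was not tested.

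Olfactory receptor genes were also higher (164 genes, median shift 0.81 in sh-LINC01116 1 and 3), with few calls (8 of 173 when every gene of the symbol stem counted) and an adjusted p = 0.965 with an estimated correlation. They were dim, with a median normalized log2 signal of -5.54 over the 6 arrays, where the median of tested genes on sh-NC 1 was -1.35. The median of that stem fell from 0.55 to 0.29 under quantile normalization, 0.28 in the authors' values and 0.11 with normexp and quantile normalization. Random lists matched on mean signal themselves shifted by a median of 0.33 (central range 0.20 to 0.46). The shift of 0.81 was above 100% of them, but such lists ignore correlation between the genes. With normexp and quantile normalization 0.19 of the pooled shift was left, so that signal range stays open. In sh-LINC01116 2 the shift was 0.17, a ratio of 0.21 to the other arrays, which argues against the knockdown as the sole cause. Yet 0.17 was itself above 100% of matched lists (central range -0.015 to 0.11), with the same limit, and how far slide and knockdown each contribute stays open.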

How the results depend on the processing

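Tests of the first slide alone, of sh-LINC01116 1 and 3 against sh-NC, and of unnamed probes were chosen after seeing the data; for changes below, the cause was not tested except where fewer arrays or more tests show it. The fit of sh-LINC01116 1 and 3 against sh-NC is the planned one without sh-LINC01116 2, and the first slide alone nearly repeats the slide block. Neither is a separate result. Against 1558 genes called, normexp with the 75th percentile gave 176, no filter on dim probes 959 (more genes tested), unnamed probes tested too 1002, the slide as a fixed block 333, the first slide alone 331, sh-LINC01116 1 and 3 alone 4502 and an adjusted p under 0.01 127. Against 382 genes at 2-fold, normexp gave 98, normexp with quantile normalization 172, the slide block 177, the first slide alone 176, sh-LINC01116 1 and 3 alone 1538, an adjusted p under 0.01 109 and an unadjusted p under 0.05 688. Leaving out 1 array gave 1 to 4502 genes, and 1 to 1538 at 2-fold. Without sh-NC 1 or sh-NC 2, GLDN alone was called, and 197 and 812 genes had an adjusted p under 0.10.

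The series text speaks of paired cells without saying what a number shares, and the values gave no sign that replicate numbers pair the samples: deviations from the group means of same-numbered arrays correlated at -0.02, -0.003 and -0.11, and no array matched its own number best. With the replicate block 253 genes were called, 235 of them at least 2-fold, as were 37 of the 95 named genes; 8 lists were called, as without it.

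LINC01116 was lower under every alternative (-1.57 to -1.92) and from -1.62 to -1.92 with 1 array left out. Of the 8 lists called, 0 were called with an estimated correlation, 4 in the authors' values, and 4 of 7 called by fry were among them; list tests with robust limma and the random slide block were not run. Of 95 named calls, 30 passed with normexp and the 75th percentile, 36 with the slide block, 36 on the first slide alone and 1 to 95 with 1 array left out. Directions turned for the ribosomal list (-0.093 under quantile normalization, -0.12 with normexp and quantile normalization, -0.14 in the authors' values), DDX5 (-0.21, -0.26 and -0.24 in the same order, -0.067 with the slide block, -0.067 on the first slide alone, -0.0050 with the random slide block), BCL2L11 (0.23 with probes averaged), PCDHB15 (0.33) and SOX5 (0.24), the last pair with normexp and the 75th percentile. Genes measured in one group only numbered 42, 32 with positive and significant in place of well above background (none of the 42 among them), 154 when 2 arrays of a group sufficed and 51 to 297 with 1 array left out. Of the rest, 1621 gene values and 149 list values kept direction and side, 591 and 32 kept direction but not the call. These totals count the fit without sh-LINC01116 2 under both of its names. Signal over background limits dim probes, 25156 to 28288 of 34127 being well above it per array.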

Other observations

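The tests on gene families, of where each array lies within its group, the neighbouring-gene test and the names PCDHB2, PCDHB14, PCDHB15, SOX2, SOX2-OT, SOX21 and SOX5 were chosen only after the data were seen.

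Families of genes with a common symbol stem and at least 8 tested members were tested with camera, 287 in all. Of these, 7 had an adjusted p under 0.05, and none with an estimated correlation. Higher were the olfactory receptor, keratin-associated protein (KRTAP, 66 genes, median 0.57, within slide 0.12, adjusted p = 0.0102, but 0.34 under quantile normalization, 0.33 in the authors' values and 0.20 with normexp and quantile normalization), large ribosomal subunit (RPL, 60 genes with pseudogenes among them, median 0.43, within slide -0.0019, adjusted p = 0.0102, but -0.06 under quantile normalization, -0.11 with normexp and quantile normalization and -0.09 in the authors' values) and taste receptor (TAS, 20 genes, median 0.53, within slide 0.26, adjusted p = 0.0134, but 0.27 under quantile normalization, 0.26 in the authors' values and 0.12 with normexp and quantile normalization) stems. The protocadherin beta genes, adhesion proteins encoded side by side in one cluster, were lower (14 genes, median log2 fold change -0.50, camera adjusted p = 0.00197, and an adjusted p = 0.965 with an estimated correlation). Their medians were -0.41, -0.47 and -0.57 in sh-LINC01116 1, 2 and 3, and 12 of 14 were lower within the slide. The family kept this direction under quantile normalization (-0.61), median scaling (-0.66) and in the authors' values (-0.62), and had a median of 0.01 with normexp and the 75th percentile. PCDHB14 (1.68-fold lower), PCDHB15 (1.60-fold lower, but 0.33 on the log2 scale with normexp and the 75th percentile) and PCDHB2 (1.39-fold lower) passed the test. In the alpha and gamma clusters of protocadherins, PCDHA11 had a log2 fold change of -0.75 (limma adjusted p = 0.034) and PCDHGC5 one of 0.90 (adjusted p = 0.046), both named after their values were seen.

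Genes of the SOX stem, transcription factors and the non-coding SOX2-OT, were lower as well (13 genes, median -0.36, camera adjusted p = 0.0134, and an adjusted p = 0.965 with an estimated correlation), with medians of -0.29, -0.35 and -0.77 in sh-LINC01116 1, 2 and 3 and the same direction under each of the 5 other scalings. Beside SOX4 (1.82-fold lower), the calls were SOX2-OT (log2 fold change -1.32), a non-coding transcript around SOX2, SOX21 (2.34-fold lower) and SOX5 (1.73-fold lower, but 0.24 on the log2 scale with normexp and the 75th percentile), while SOX2 itself had a log2 fold change of -0.26 (adjusted p = 0.121). HOXD genes as a family of 8 had a median of -0.41, with -0.34, -0.41 and -0.42 in the 3 arrays, and a median of -0.16 with normexp and the 75th percentile (camera adjusted p = 0.0134, and an adjusted p = 0.965 with an estimated correlation).

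One hypothesis was that a gained or lost stretch of the genome in the knockdown line could shift neighbouring genes together. Over 3111 windows of 50 neighbouring genes, the largest median shift shared by all 3 sh-LINC01116 arrays was 0.23, below the 0.3 that was asked for, and 0.23 was also the largest shift in sh-LINC01116 2, where 100 shuffled gene orders reached 0.25. This argues against a large regional change common to the 3 arrays and leaves smaller ones open.

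The local background of the spots of sh-NC 1 lay between that of sh-NC 2 and sh-NC 3 in 30.7% of spots, near the 33.3% of independent arrays, whereas its gene signal did so in 72.6% of genes. The scan thus seems to be its own, and whether the RNA was a mixture of the others or lay midway by itself was not tested. The array weight of sh-NC 1 was 25.3, against 0.27 to 1.19 for the others.

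In the ACTB probe the normalized log2 signal was 4.70 to 5.06 on the sh-NC arrays, 4.97 on sh-LINC01116 2, 6.44 on sh-LINC01116 1 and 8.04 on sh-LINC01116 3. The 75th percentile subtracted was that of 733 on sh-LINC01116 1 and 636 on sh-LINC01116 3, against 2005 to 2026 on the sh-NC arrays. The scaling alone thus raises these values on the dimmer arrays, and they do not by themselves show more ACTB RNA there.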
